A study of Mus musculus with 2 samples.

How the data were processed

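ChIP-seq for H3K9me3 was carried out on mouse neural tube of embryonic day 11.5, and the labels give 2 biological replicates of 1 group, with fragments selected at a size range of 300 to 500. The values used here came from 4 deposited peak lists in narrowPeak format on the mm10 assembly. Per the deposited descriptions, the lists of replicate 1 and replicate 2 were each made from that replicate's alignments with 2 further files named as inputs. A pooled list was made from both replicates' alignments with 2 further files, and the replicated list was drawn from the pooled list and both replicates' lists. The aligner, the peak caller and their settings are not given in the sources used here. Each peak's signal value was taken as the authors deposited it, and how that signal was scaled is not stated. The deposited −log10 p and −log10 q of each peak were likewise used as written by the authors, and the largest p of any list was 0.00962, in the pooled list. Signal and p were used only to describe, rank or filter peaks within their own list.

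No read counts accompanied the lists, so the sequencing depth is unknown and no interval that needs it was computed. All 8051 replicated peaks were identical in position to a pooled peak. Of the 7816 on chromosomes, 6851 overlapped a peak of each replicate by at least 1 bp, so the rest met whatever rule made the list in another way. The comparisons used the peaks on chromosomes 1 to 19, X and Y, and peaks on other contigs are described apart. No peak ran past the end of its chromosome in the reference used, GRCm38.p6 with soft-masked sequence and GENCODE M21 genes, which is the same build as mm10. How the sequence was masked is not stated in the reference.

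Overlap between the replicates was counted when the shared bases made up at least 50% of either peak. Chance levels came from circular shifts, in which all peaks of a list were moved by 1 random distance along the joined chromosomes without N, so that peak lengths and spacing were kept. There were 10000 shifts per test, and 1000 for sequence composition, and every such permutation test was two-sided. The smallest p they can give is 0.0002, and 0.002 for composition. P-values were adjusted by Benjamini and Hochberg over the chromosomes, over the 4 feature classes and over the 26 gene lists, and an adjusted p under 0.05 counted as passing. Promoters reached 1 kb to either side of a protein-coding or long noncoding gene's start, and a peak was classed by its midpoint as promoter, exon, intron or intergenic, in that order. A gene counted as carrying a peak when at least 1 bp of a peak lay between 2 kb upstream of its start and its end. Domains joined replicated peaks within 10 kb and held at least 2 peaks.

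The gene lists were KRAB-type and other Zfp zinc finger genes, olfactory receptors, vomeronasal receptors, clustered protocadherins, Hox, cytochrome P450, serpin, major urinary protein, Klr receptor, keratin-associated protein, defensin, Rhox, Mage, UDP-glucuronosyltransferase, replication-dependent histone and ribosomal protein genes, imprinted genes, genes at imprinted germline differentially methylated regions, germline, pluripotency, neural progenitor and neuronal genes, erythroid and blood genes, muscle, heart, liver and gut genes, H3K9 methylation and silencing genes, and housekeeping genes. All 23 genes at germline differentially methylated regions were also among the 50 imprinted genes, and 3 further genes stood in more than 1 list. Along Zfp genes, the share of bases under peaks was compared between the last and the first of 3 equal parts of the gene body by a sign-flip permutation test. The median signal value of peaks in Zfp gene windows was compared with that of all other peaks by a permutation test, and both tests used 100000 resamples. The smallest p these can give is 1e-05.

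The genes named were, in each list, up to 4 members with the highest signal value in a replicated peak and, in lists of 25 genes or fewer, any member with a replicated peak. Named as well were the genes at the 10 replicated peaks of highest signal value, the 10 protein-coding genes with the most bases under replicated peaks and the genes of the 5 longest domains. The lists, tests, naming rule and alternatives were fixed before the data were examined, and anything chosen later is said to be so. The alternatives were each replicate's own list, the pooled list, the upper 50% of peaks by signal value, peaks of q under 0.01, other overlap, window, promoter and joining distances, shifts within each chromosome, Fisher's exact test and other scales of the signal value. Fisher's exact test compared a list with all other protein-coding genes and, unlike the shifts, took no account of gene length. One alternative was added after the data were seen, the removal of peaks in which over 10% of 31-mers occurred again in the assembly. The counts of genes with a peak within 1 kb of the start or on the first exon or the last coding exon were also made after the data were seen. So was a comparison of the gene lists with 100 sets of random positions, which had the widths of the replicated peaks and, of 2000 drawn for each peak, the nearest GC shares, with the larger of the SDs of these positions and of the shifts as the spread. The GC of these positions differed from that of the peaks by a mean of 0.653 percentage points, and by 26.9 at most. The positions were drawn independently for each peak, so unlike the shifts they did not keep the peaks' clustering.

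The tests were checked on simulated peaks. For the gene lists, 1.90% of lists had p under 0.05 in 200 simulated sets with no effect, and a planted list was recovered in 20 of 20 sets. For the replicate overlap, 30.1% of peaks were found shared where 30% had been planted. With no effect, p was under 0.05 in 3.75% of feature shares, 4.07% of chromosomes, 4.66% of gene end tests and 5.4% of signal tests. For lists, features and chromosomes, the sets with no effect were shifted peaks tested against shifts. Their rates therefore check the calculation and not whether shifts suit the data. In the signal tests the peaks were drawn at random, so that rate does not cover peaks that cluster. The sequence measures returned the values set in test sequences. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, numba 0.67.0 and pandas 2.3.3, and plots used matplotlib 3.10.9.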

Results

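H3K9me3, a histone modification of heterochromatin, was mapped by ChIP-seq in the mouse neural tube, the embryonic structure that forms the brain and spinal cord, at embryonic day 11.5. The 2 biological replicates of the single group were pools of neural tubes from 109 and 88 embryos of both sexes of strain B6NCrl. The deposited lists held 35212 peaks for replicate 1, 42781 for replicate 2, 14195 for the pooled alignments and 8051 replicated peaks. Replicated peaks had a median width of 316 bp and covered 3.24 Mb in all. Those on chromosomes covered 0.115% of the chromosomes' sequence without N. A q below 0.01 was recorded for 1694 replicated peaks, and the depth of sequencing is unknown.

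The design allows 1 comparison between samples, replicate against replicate, which asks whether both pools of embryos carried the mark at the same places. Both replicates had peaks at the start of Dazl, which encodes a germ cell RNA-binding protein, with signal values of 6.29 and 5.86. From 2 kb upstream of its start to its end, Pcdhga1, a clustered protocadherin gene whose family gives neurons their surface identity, carried 108 peaks in replicate 1 and 119 in replicate 2. In the same window of Zfp873, which belongs to the large Zfp family of zinc finger genes, the counts were 16 and 19. These genes were named for their strong replicated peaks, and the replicated list was drawn partly from both replicates' lists. Their peaks in both replicates are therefore examples and not evidence of agreement. Over the whole genome most peaks of either replicate had no match in the other. Most peaks in these lists were weak, with q under 0.05 recorded for 27.6% in replicate 1 and 25.2% in replicate 2. A missing match therefore need not mean a difference between the pools. Of the 34896 peaks of replicate 1 on chromosomes, 18.96% were matched, and of the 42472 of replicate 2, 15.7%. These shares count 1 overlap from either side, with 6616 and 6668 matched peaks. They differ mainly because the lists differ in length, so no spread between samples can be drawn from them. Shifted peaks were matched in 0.502% and 0.412%, so the observed shares were 37.8 and 38.1 times as high (permutation p = 0.0002 for each, the smallest the shifts can give).

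Matching was most frequent among the peaks of highest signal value. It reached 64.1% and 65.4% in the top 1000 peaks of replicates 1 and 2, and 41.2% and 39.5% in the top 5000. Matched peaks were wider than unmatched ones, with medians of 291 against 218 bp in replicate 1 and 285 against 217 bp in replicate 2. Bases covered in both replicates made up 10.4% of the bases covered in either, against 0.193% for shifted peaks (permutation p = 0.0002, the smallest the shifts can give). The share was 16.5% when only peaks of q below 0.01 were kept. Of those peaks, 21.6% in replicate 1 and 21.1% in replicate 2 were matched by a peak of q below 0.01 in the other replicate. Shifted peaks were so matched in 0.0916% and 0.0874%. The top 1000 and top 5000 were instead matched against all peaks of the other replicate, so their shares cannot be set beside these.

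**Figure D1:**
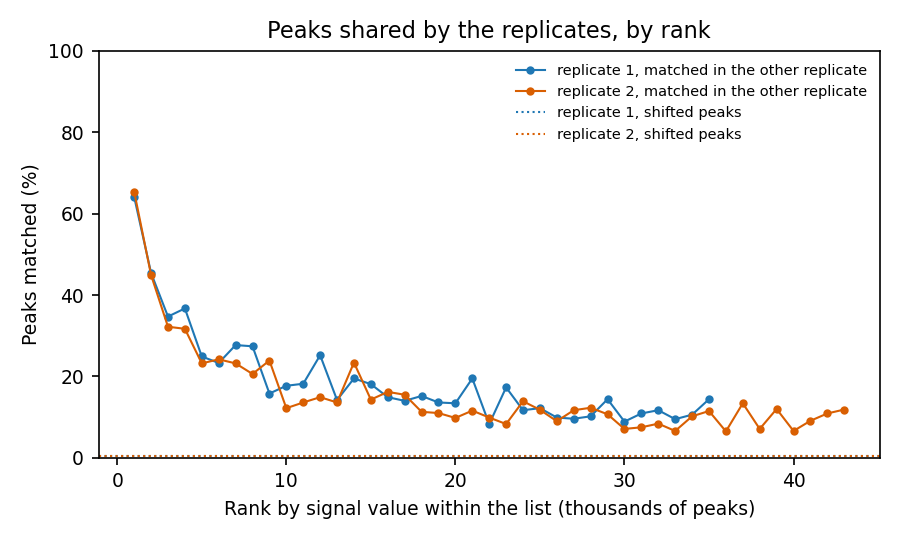
Percent of each replicate's peaks matched in the other replicate, for successive groups of 1000 peaks ordered by signal value, with dotted lines for shifted peaks. The first 1000 peaks were matched at 64.1% in replicate 1 and 65.4% in replicate 2, against shifted levels of 0.502% and 0.412%.

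The remaining comparisons ask where in the genome the replicated peaks lay. Chromosome 7 held 1622 of the 7816 replicated peaks on chromosomes, 3.87 times the number its length would give, followed by chromosome 17 with 1.96 times and chromosome 18 with 1.69 times. The X chromosome held 118 peaks, 0.244 times its share, and the Y chromosome held 4, or 0.0154 times. The expected numbers came from length alone, although the pools held embryos of both sexes. Copy numbers of the X and Y chromosomes were therefore not accounted for, in the ratios or in the shifts. The count on the Y chromosome was the only one to pass the test (permutation adjusted p = 0.0294), while chromosome 7 did not pass against shifted peaks, which kept their clusters (permutation adjusted p = 0.773). In the lists of single replicates, chromosome 7 held 2.53 and 2.24 times its share, and the Y chromosome 0.00603 and 0.00424 times. The count on the Y chromosome no longer passed among the upper 50% of peaks by signal value (permutation adjusted p = 0.260) or at q below 0.01 (permutation adjusted p = 0.594). Of the Y chromosome's sequence 96.3% was soft-masked, against 36.4% of all chromosomes.

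**Figure D2:**
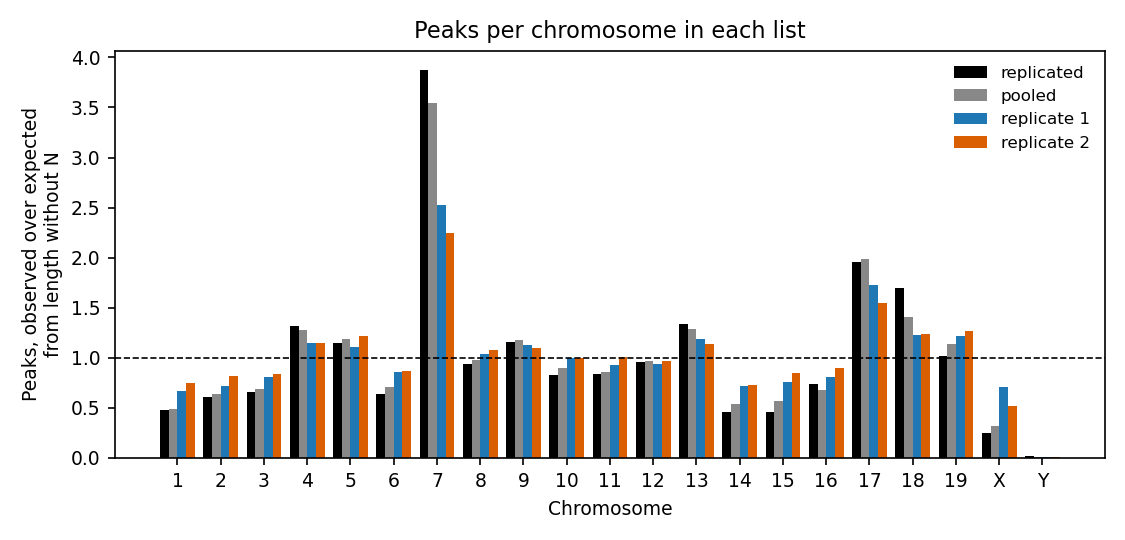
Peaks per chromosome over the number expected from its length without N, for the replicated, pooled and single-replicate lists, with a dashed line at 1. Chromosome 7 stands highest in all 4 lists, at 3.87 in the replicated list, and the Y chromosome lowest, at 0.0154.

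Exons and promoters held more replicated peaks than shifted peaks gave. Exons held 8.79% of peaks against 3.64%, a ratio of 2.42, and promoters held 4.39% against 2.21%, a ratio of 1.98 (permutation adjusted p = 0.0004 for each). Introns held fewer, 31.3% against 39.9% (permutation adjusted p = 0.00560), and intergenic sequence held 55.5% against 54.3%, which did not pass (permutation adjusted p = 0.636). At q below 0.01 the ratios were 3.87 for exons and 3.02 for promoters, and the lower share in introns no longer passed (permutation adjusted p = 0.0603). The peaks were richer in G and C than shifted peaks, at 47.3% against 41.7%, and had fewer soft-masked bases, at 22.0% against 36.4% (permutation p = 0.002 for each, the smallest the shifts can give). The shifts did not match the peaks in either share, and features were not compared with positions that did. How far the exon and promoter ratios depend on these shares is therefore not known. How reads from repeated sequence were placed is not known, so the lower masked share cannot show that the mark avoids such sequence. Their ratio of observed to expected CpG was 0.202 against 0.190 (permutation p = 0.0320). In the pooled list it was 0.191 (permutation p = 0.875), and in replicates 1 and 2 it lay below the shifted level at 0.186 (permutation p = 0.212) and 0.189 (permutation p = 0.721).

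Of 21938 protein-coding genes, 1633 (7.44%) carried a replicated peak. Of the 26 gene lists, 7 held more genes with a peak than shifted peaks gave and none held fewer, even at an unadjusted p under 0.05. The clustered protocadherins stood highest by share, with a peak at 53 of 57 genes against 6.12 for shifted peaks, a ratio of 8.66 (permutation adjusted p = 0.00130). A peak lay within 1 kb of the start at 46 of the 53, but peaks were dense over the whole cluster, and starts were not compared with the rest of it. Pcdhga1, Pcdhga2, Pcdhga3 and Pcdhgb1 shared their strongest peak, at position 37746720 to 37747537 of chromosome 18, with a signal value of 7.66. Genes of this cluster overlap, so that 1 peak can count for several of them. In the lists of replicates 1 and 2 all 57 genes carried a peak, with ratios of 2.48 and 2.21. The list passed under all 10 alternatives, with ratios up to 94.3 when the window was limited to 2 kb either side of the start. Random positions of GC near that of the peaks were tried after the results were seen. They fell on a mean of 13.01 genes (SD 9.74), a ratio of 4.07.

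Imprinted genes, which are expressed from 1 parental copy, carried a replicated peak at 35 of 50 genes against 3.87 for shifted peaks, a ratio of 9.04 (permutation adjusted p = 0.00130). For the 23 of them at germline differentially methylated regions, where the methylation that controls imprinting is set in egg or sperm, the count was 18 against 1.57, a ratio of 11.5 (permutation adjusted p = 0.00130). The highest signal values were 5.14 at Peg12, 5.01 at a peak shared by Nespas and Gnas, and 4.71 at Grb10. Snrpn had a highest value of 4.41 and Nnat 4.41, Mest 4.25, Peg10 4.04, Impact 4.04, Peg3 3.97, Zrsr1 3.97 and Airn 3.88. The lowest of these 18 genes were Inpp5f at 3.77, Peg13 at 3.73, Cdh15 at 3.67, Plagl1 at 3.64, Nap1l5 at 3.41, Kcnq1ot1 at 3.37 and Meg3 at 3.29. The genes of this list without a replicated peak in their window were H19, Mcts2, Rasgrf1, Slc38a4 and Zdbf2, which are named after their values were seen. A peak lay within 1 kb of the start at 16 of the 35 imprinted genes and at 9 of the 18 at such regions. The windows followed the genes, and the differentially methylated regions themselves were not compared with the peaks. A peak in a window, or its absence, is therefore not one at the region. In replicates 1 and 2 taken alone, the ratios for imprinted genes were 2.72 and 2.28, and for those at germline differentially methylated regions 3.23 and 2.61. With the window limited to 2 kb either side of the start they were 36.6 and 45.2, and both lists passed under all 10 alternatives. Against random positions close to the peaks in GC, a test chosen after the results were seen, the ratios were lower, at 4.16 and 5.59.

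Germline genes, which act in meiosis and germ cell development, carried a replicated peak at 9 of 42 genes against 2.90 for shifted peaks, a ratio of 3.11 (permutation adjusted p = 0.0113). Random positions of GC near that of the peaks were tried after the results were seen. They fell on a mean of 5.34 of these genes, which lowers the ratio to 1.69, a difference under 2 SD. Those positions did not keep the peaks' clustering, so the lower ratio cannot be put down to GC alone. At 7 of the 9 the peak lay within 1 kb of the start. The highest signal value was 4.86 at Dazl, followed by 4.12 at Ddx4, a germ cell RNA helicase, 4.04 at Sycp1, a part of the synaptonemal complex, and 3.73 at Sohlh2, a transcription factor of early germ cells. With the window limited to 2 kb either side of the start, the ratio was 18.4 (permutation adjusted p = 0.00130). The list did not pass in replicate 1 alone, with a ratio of 1.42 (permutation adjusted p = 0.223), in replicate 2 alone, with 1.32 (permutation adjusted p = 0.336), or at q below 0.01, with 3 genes and a ratio of 4.77 (permutation adjusted p = 0.211).

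Zfp zinc finger genes, many of which encode KRAB proteins that recruit silencing to repeats, carried a replicated peak at 118 of 425 genes against 20.3 for shifted peaks, a ratio of 5.82 (permutation adjusted p = 0.00130). The strongest of these peaks lay at Zfp981 on chromosome 4, with a signal value of 8.77, at Zfp513 on chromosome 5 with 7.19, at Zfp600 on chromosome 4 with 6.79 and at Zfp873 on chromosome 10 with 6.56. Zfp873 had 15 replicated peaks over 8.70 kb and Zfp981 had 13 over 6.26 kb. In contrast to the protocadherins, 2 of the 118 genes had a peak within 1 kb of the start, and with the window limited to 2 kb either side of the start the list did not pass, at a ratio of 2.11 (permutation adjusted p = 0.430). In replicates 1 and 2 alone the ratios were 2.32 and 1.99, and at q below 0.01 the ratio was 13.5.

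Vomeronasal receptors, which sense pheromones, carried a replicated peak at 57 of 329 genes against 10.2 for shifted peaks, a ratio of 5.56 (permutation adjusted p = 0.00728). Vmn1r66, Vmn1r74 and Vmn2r53 had the highest signal value, 4.67 for each, followed by Vmn1r181 with 4.51, and all 4 genes lie on chromosome 7. With shifts kept within each chromosome the ratio was 2.99, against other protein-coding genes it was 2.38, in replicates 1 and 2 alone it was 2.09 and 1.72, and at q below 0.01 the list did not pass, with 8 genes and a ratio of 3.74 (permutation adjusted p = 0.211). Olfactory receptors carried one at 70 of 1135 genes against 20.5 for shifted peaks, a ratio of 3.41 (permutation adjusted p = 0.0282). Their highest signal values were 5.30 at Olfr1349, 4.67 at Olfr341, 4.51 at Olfr403 and 4.27 at Olfr358. This result depended on how chance was set. Against other protein-coding genes, the share of olfactory receptor genes with a peak was 0.821 times as high (Fisher's exact test, adjusted p = 0.268). That test takes no account of gene length, and shifted peaks fell on only 20.5 of these genes, so its ratio below 1 is not a depletion. With shifts kept within each chromosome the ratio was 2.45 (permutation adjusted p = 0.142). The list did not pass in replicate 1 alone, with a ratio of 1.70 (permutation adjusted p = 0.0579), in replicate 2 alone, with 1.49 (permutation adjusted p = 0.0849), or at q below 0.01, with 2.67 (permutation adjusted p = 0.291).

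The gene lists of neural tube cell types carried few replicated peaks or none. Among the 35 neural progenitor genes Prom1, which encodes a membrane protein of neuroepithelial cells, had a peak of signal value 3.08 in an intron, and the 32 neuronal genes had none (permutation adjusted p = 1 and 0.324). None was found at the 39 Hox genes, 18 pluripotency genes, 18 erythroid and blood genes, 24 genes of muscle, heart, liver and gut, 24 housekeeping genes, 80 ribosomal protein genes, 22 major urinary protein genes or 57 keratin-associated protein genes (permutation adjusted p = 1 for each list). Against other protein-coding genes, the ribosomal protein genes alone held fewer (Fisher's exact test, adjusted p = 0.0137). That test takes no account of gene length, and shifted peaks fell on only 1.12 of the 80 genes, so it cannot show a depletion. Of the 26 genes of H3K9 methylation and silencing, Atf7ip, Smchd1 and Trim28 had peaks of 3.64, 3.25 and 3.10 (permutation adjusted p = 1). The shifted means of the lists without a peak lay between 0.384 and 2.38 genes, so the shifts could not show a count below chance for them. Random positions of GC near that of the peaks were tried after the results were seen. They fell on a mean of 4.76 neuronal genes (SD 1.56) and 2.28 blood genes (SD 1.08). The count of 0 lay more than 2 SD below both, and the other lists without a peak lay within 2 SD. Those positions did not keep the peaks' clustering, which can by itself spread them over more genes. The comparison therefore cannot show a depletion at neuronal or blood genes. In replicates 1 and 2 taken alone the direction turned, with a peak at 9 and 11 neural progenitor genes (ratios of 1.45 and 1.496) and at 11 and 13 neuronal genes (1.19 and 1.21). The ratios also lay above 1 for pluripotency genes (2.499 and 1.38), erythroid and blood genes (1.89 and 1.16) and genes of muscle, heart, liver and gut (1.65 and 1.56), and none of these 5 lists passed (permutation adjusted p of 0.130 or more).

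Among the other families of tandem genes, 11 of 98 cytochrome P450 genes carried a replicated peak, a ratio of 2.48, with signal values of 4.51 at Cyp2c29, 4.20 at Cyp3a57, 4.12 at Cyp3a11 and 4.04 at Cyp2b9 (permutation adjusted p = 0.223). This list passed in the pooled list of peaks, with 20 genes (permutation adjusted p = 0.0494), and in replicate 2 alone, with 44 (permutation adjusted p = 0.0208). Of 22 UDP-glucuronosyltransferase genes 9 did, all of the Ugt1a cluster, a ratio of 5.59 (permutation adjusted p = 0.202), and the list passed at q below 0.01, with a ratio of 26.6 (permutation adjusted p = 0.0416). In replicates 1 and 2 alone its ratio was only 1.28 (permutation adjusted p = 0.947) and 1.45 (permutation adjusted p = 0.742), and the 9 genes overlap at 1 locus, so that the same peaks count for several of them. The counts were 4 of 26 Klr receptor genes, led by Klra2 at 4.04, and 4 of 64 defensin genes, led by Defb35 at 3.37 (permutation adjusted p = 0.223 for each). Serpin genes had 5 of 61, led by Serpinb6d at 4.04 (permutation adjusted p = 0.472), and histone genes 2 of 67, Hist1h2ba and Hist1h2aa, which shared a peak of 2.78 and had none in replicate 2 (permutation adjusted p = 0.525). Rhox genes had 1 of 34, Rhox10 at 3.10, where 8 bp of the peak lay in the window and replicate 1 had no peak (permutation adjusted p = 0.986), and Mage genes 1 of 21, Magel2 at 3.73 (permutation adjusted p = 1).

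**Figure D3:**
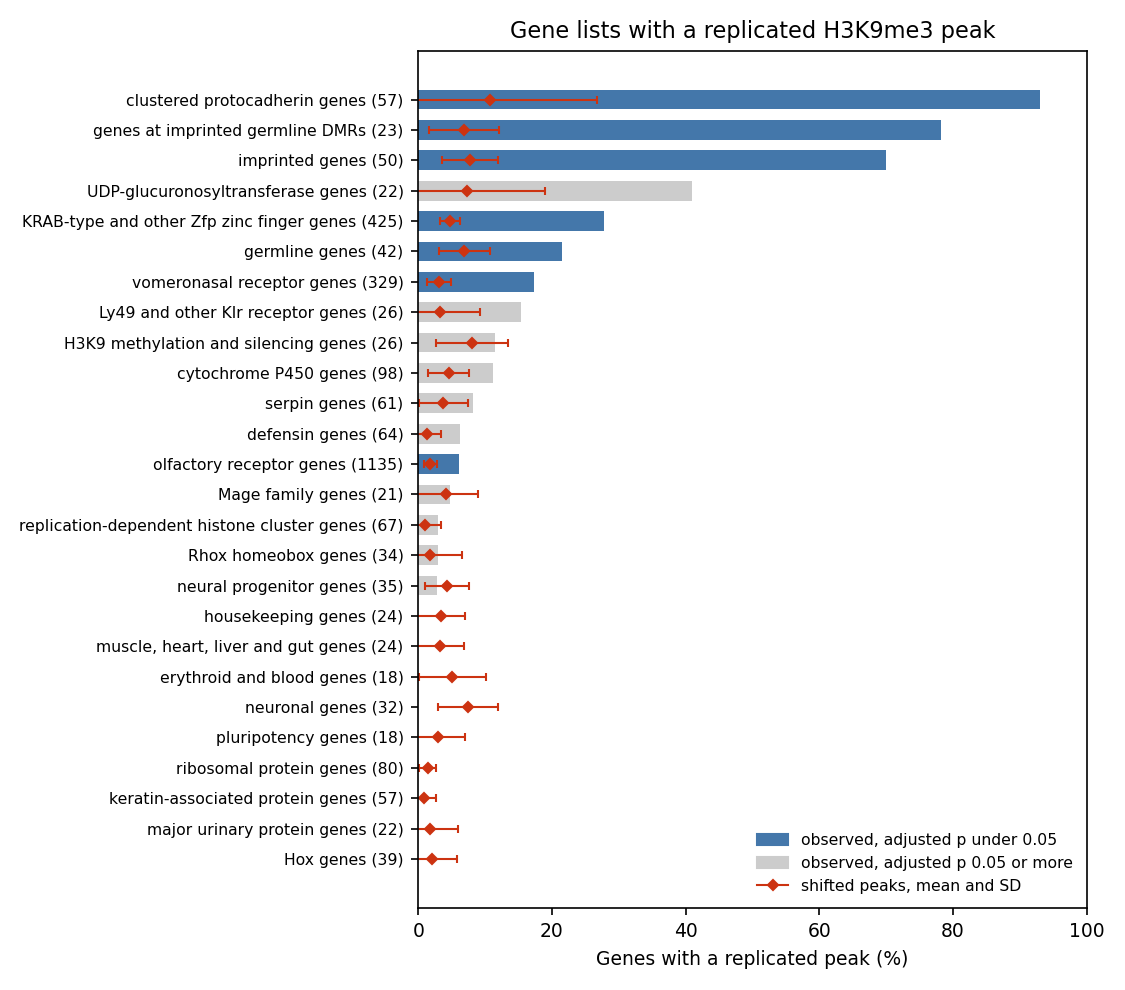
Percent of each list's genes with a replicated peak (bars, blue where the adjusted p was under 0.05, with the number of genes in brackets) and the mean and SD of shifted peaks (diamonds). Clustered protocadherins stand highest at 93.0%, genes at imprinted germline differentially methylated regions reach 78.3% and imprinted genes 70%.

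Along the Zfp genes the mark was placed toward the end of the gene, where the zinc fingers of this family are usually encoded in a single last coding exon. Replicated peaks covered 3.00% of bases in the first of 3 equal parts of the gene body, 7.89% in the middle and 16.2% in the last. The last part exceeded the first by 13.2 percentage points ± 1.64 (SE, n = 117 genes with a peak on the gene body), with 90 genes higher in the last part and 15 in the first (permutation p = 1e-05, the smallest the resamples can give). A peak lay on the last coding exon of 66 of the 117 genes (56.4%) and on the first exon of none, whereas among 1431 other protein-coding genes with a peak 12.1% had one on the last coding exon and 11.3% on the first exon. Those other genes had 3.51% of bases covered in the last part and 4.26% in the first. The exon counts took any overlap and were not adjusted for exon length, unlike the shares of bases in equal parts. Neighbouring Zfp genes are not independent, and the last part was higher in 64 of the 79 clusters they formed. In replicates 1 and 2 alone the difference was 9.19 and 7.09 percentage points, over 200 and 211 genes. Replicated peaks in Zfp gene windows also had a higher median signal value than all others, 3.67 for 386 peaks against 3.25 for 7430 (permutation p = 1e-05, the smallest the resamples can give). This test treated single peaks as independent, but the 386 peaks lay at 118 genes, with 15 at Zfp873. Its p therefore overstates the evidence, and no test by cluster was run for the signal value.

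**Figure D4:**
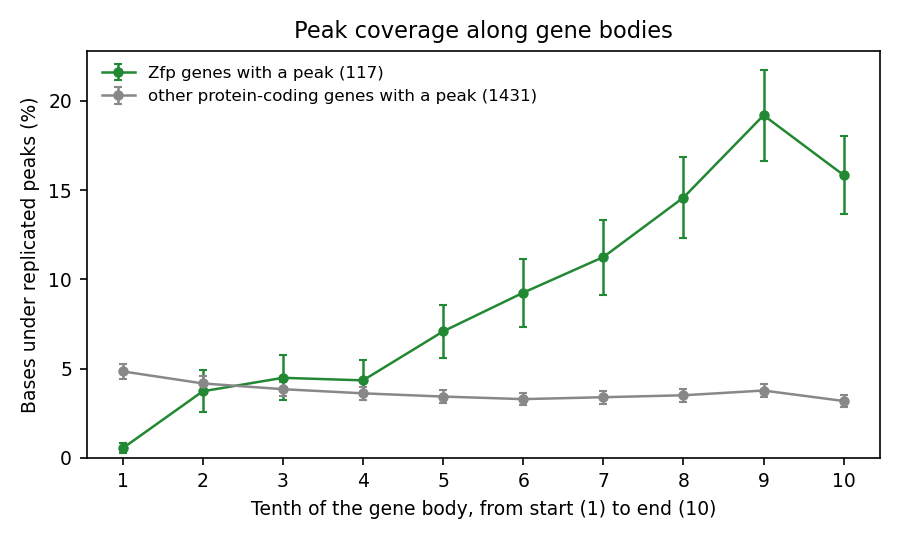
Percent of bases under replicated peaks in each of 10 equal parts of the gene body, from start to end, as mean and SE over genes with a peak, for 117 Zfp genes and 1431 other protein-coding genes. The Zfp genes go from 0.538% in the first part to 19.2% in the ninth, while the other genes start at 4.84%.

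Replicated peaks were grouped along the chromosomes, with 4480 of 7816 (57.3%) in 1032 domains. In this list the protocadherin cluster on chromosome 18 held the 3 longest. The longest ran over 116 kb, from 37655013 to 37771045, where 85 peaks covered 53.1% of the sequence from Pcdhga1 to Pcdhga12. Another ran over 109 kb from 37248989 to 37357597, from Pcdhb1 to Pcdhb8, with 33 peaks, and a further one over 101 kb from 36930285 to 37031260, from Pcdha1 to Pcdha12, with 39 peaks. The 10 protein-coding genes with the most bases under peaks all lay there. They were Gm42416, Gm37013 and Gm37388, which span much of the cluster and had 120 to 124 kb covered, and Pcdhga1 to Pcdhga5, Pcdhgb1 and Pcdhgb2, with 44.4 to 59.7 kb. The longest domain of the pooled list and of replicate 1 lay on chromosome 7 instead, from 17896174 to 18142999 (247 kb) and from 17885749 to 18149573 (264 kb), and that of replicate 2 in the protocadherin cluster (182 kb). The number of domains depended on the list, with 1759 in the pooled list, 4690 in replicate 1 and 6390 in replicate 2.

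A domain of 99.5 kb on chromosome 1, from 88211402 to 88310888, was the most densely covered of the 5 longest, with 44 peaks over 74.0% of its sequence. It holds the shared last exons of the Ugt1a genes (Ugt1a1, Ugt1a2, Ugt1a5, Ugt1a6a, Ugt1a6b, Ugt1a7c, Ugt1a8, Ugt1a9 and Ugt1a10), which conjugate bilirubin and drugs, and Mroh2a, Hjurp, a chaperone of the centromeric histone, and part of Trpm8, the cold-sensing channel. Its peaks had −log10 p values 2.71 times those of peaks of nearest signal value elsewhere. The fifth domain, on chromosome 7 from 18009669 to 18084191, held 25 peaks at Ceacam13, Ceacam12 and Gm44613.

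**Figure D5:**
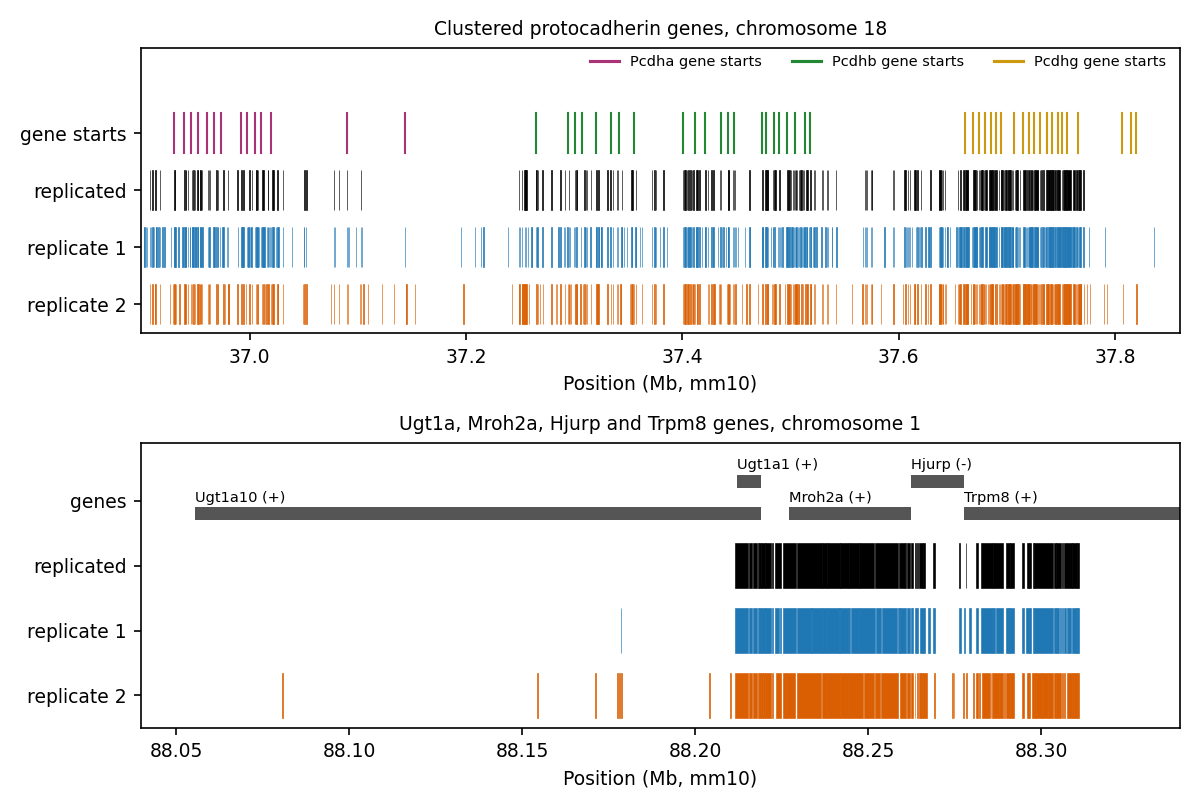
Peaks of the replicated list and of each replicate along the clustered protocadherin genes on chromosome 18 (with gene starts) and the Ugt1a to Trpm8 genes on chromosome 1, positions in Mb on mm10. The gamma protocadherin domain was 53.1% covered by replicated peaks and the domain from Ugt1a to Trpm8 74.0%.

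The replicated peak of highest signal value, 13.2, lay on chromosome 18 from 3117838 to 3119030, with Vmn1r238 as the nearest gene at 3.46 kb. Of the 10 strongest peaks, 4 more lay near the assembled start of a chromosome, namely 1 on chromosome 4 nearest Vmn1r2, 1 on chromosome 6 nearest Gm8579 and 2 on chromosome 16 nearest Gm49504. Another lay at 90740955 on the Y chromosome, nearest Gm21860. The others overlapped Zfp981 with Gm26573 and 1700095A21Rik (8.77), Klf14, a zinc finger transcription factor gene on chromosome 6 (8.76), Gm49692 on chromosome 12 (8.36), and the gamma protocadherin genes (7.66).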

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

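The ratio of −log10 p to that of peaks of similar signal value was chosen as a test only after the result was seen. Sequence outside the chromosomes, which no comparison of the report used, also carried peaks. Unplaced and unlocalised contigs held 235 replicated peaks, 269 pooled peaks, 316 peaks of replicate 1 and 309 of replicate 2. No control samples were there to set these counts against. Replicated peaks were 14.9 times as dense on contigs as on chromosomes, at 44.1 against 2.95 per Mb, and 57 of them lay on the contig JH584304. The ratio was 9.59 in the pooled list and lower in single replicates, at 4.49 and 3.61. Among the 100 replicated peaks of highest signal value, 23 lay on contigs and 17 within 1 Mb of the assembled start of a chromosome, a stretch that holds 0.793% of the joined chromosomes.

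Reads from repeat copies missing from the assembly could raise both signal and background in these 40 peaks. If the signal value is relative to background, which is not stated, this would give them a stronger p than their signal value alone. Their median −log10 p was 1.24 times that of peaks of nearest signal value, with quartiles of 0.992 and 1.49, and the other 60 of the top 100 had 1.18, so the test did not decide. Sequence repeated within the assembly is also a candidate explanation. For the 17 peaks near chromosome starts, 11.97% of 31-mers had another copy, against 4.39% in other replicated peaks on chromosomes and 10.1% in the rest of the top 100, and the contig peaks had no sequence to test. Both explanations stay open, and no biological explanation was tested because the design has 1 group.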

How the results depend on the processing

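The removal of peaks with repeated 31-mers was chosen only after the data were seen, and all other settings were planned. No paired analysis was possible because the series has 1 group. Of 363 values of results under alternative settings, 297 kept their direction and their side of the threshold (or stayed within the range set for values without a test). The replicate overlap, shared bases, exon and promoter ratios, GC and soft-masked shares, Zfp gene ends, Zfp signal, and the lists of protocadherins, imprinted genes and genes at germline differentially methylated regions did so under every alternative run for them. The others follow, and the cause was not tested. Ranked by p value, 70.3% of the top 1000 and 42.9% of the top 5000 peaks were matched, and 75.5% of the top 500 and 30.96% of the top 10000 by signal value. The number of chromosomes that passed fell from 1 to 0 in the upper 50% of peaks by signal value, with the Y chromosome at 0.0308, and to 0 at q below 0.01, with it at 0.0797. Among features, the intron ratio was 0.812 at q below 0.01, and the intergenic ratio crossed 1, at 0.998 in the upper 50%, 0.863 at q below 0.01, and 0.996 to 1.03 in single replicates. Lists that lost their call were olfactory receptors (2.67 at q below 0.01, 2.45 with shifts within chromosomes, and turned at 0.821 by Fisher's exact test), vomeronasal receptors (3.74 at q below 0.01), germline genes (4.77 at q below 0.01) and Zfp genes (2.11 near starts). With 1 replicate left out, the ratio was 1.49 to 1.70 for olfactory receptors and 1.32 to 1.42 for germline genes, and among lists that had not passed it crossed 1 for Mage (0.531 to 0.627), histone (0.288 to 0.721), pluripotency (1.38 to 2.499), neural progenitor (1.45 to 1.496), neuronal (1.19 to 1.21), blood (1.16 to 1.89) and muscle, heart, liver and gut genes (1.56 to 1.65). In the pooled list it crossed 1 for Hox (1.45), Mage (0.707) and pluripotency genes (2.19). It fell to 0 for Rhox and histone genes in the upper 50% and at q below 0.01, for defensin, Mage and silencing genes at q below 0.01, for Klr and silencing genes near starts, and for Rhox genes with 50% of the peak inside the window. Silencing genes were at 0.899 in the upper 50%. By Fisher's exact test defensin genes were at 0.839, Rhox at 0.395, Mage at 0.640 and histone genes at 0.400. Calls were gained by cytochrome P450 genes in the pooled list (2.63) and replicate 2 (1.71), by UDP-glucuronosyltransferase genes, whose 9 with a peak overlap at 1 locus, at q below 0.01 (26.6) and by Fisher's exact test (5.52) but not in single replicates (1.28 to 1.45), and by ribosomal protein genes, below other genes, by Fisher's exact test (0). The CpG ratio was 0.191 in the pooled list, 0.186 to 0.189 in single replicates and 0.186 in 200 bp around the midpoint. Domains numbered 1759 in the pooled list and 4690 to 6390 in single replicates, which hold more peaks. The unknown depth limits what an absent peak can show, and ratios by Fisher's exact test take no account of gene length.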

Other observations

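The tests of gene name families, of random positions matched in GC, and of −log10 p in the Ugt1a to Trpm8 domain were chosen only after the results were seen. Gene families that no list held also carried the mark on chromosome 7. Among 226 families of at least 10 protein-coding genes with a shared name stem, the secretoglobins passed the shift test, with a replicated peak at 11 of 34 genes against 0.355 for shifted peaks, a ratio of 30.99 (permutation adjusted p = 0.0452). An unadjusted p under 0.05 was seen for 5 of the 226 families. Members of the secretoglobin family are secreted proteins, and 10 of the 11 lie on chromosome 7, among them Scgb2b2, Scgb2b24 and Scgb1b30. The Nlrp family, with members that act in oocytes such as Nlrp5, had 9 of 17 genes with a peak, a ratio of 7.49 (permutation adjusted p = 0.0678), and the Ceacam family of adhesion molecules had 8 of 15, a ratio of 18.6 (permutation adjusted p = 0.0753). Neither of these passed. Outside 100 kb of the genes of the 7 lists that passed, chromosome 7 held 812 peaks, 3.40 times the number its remaining length would give.

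The excess of peaks at Zfp genes, protocadherins and chemosensory receptors was weighed against reads shared between paralogs and against GC content. Without peaks in which over 10% of 31-mers were repeated in the assembly, which left 6745 of 7816 peaks, the ratios were 5.97 for Zfp genes, 9.21 for protocadherins, 5.33 for vomeronasal receptors and 3.45 for olfactory receptors, all with adjusted p under 0.05, which argues against shared reads. The gene windows of vomeronasal and olfactory receptors had 37.4% and 37.6% GC, below the genome's 41.7%, although peaks as a whole were richer in GC. In 100 sets, random positions with the widths and nearest GC shares of the peaks fell on a mean of 37.5 Zfp genes (SD 5.23) and 13.01 protocadherins (SD 9.74), and the peaks fell on 3.148 and 4.07 times as many, with ratios of 6.07 for vomeronasal and 3.82 for olfactory receptors, 4.16 for imprinted genes and 5.59 for those at germline differentially methylated regions, but 1.69 for germline genes (9 against 5.34), a difference under 2 SD. The random positions did not keep the peaks' clustering, which can by itself spread them over more genes. Their mean was above that of shifted peaks also for Mage genes, of 39.0% GC (1.49 against 0.884), though not for the receptor lists. The higher means for Zfp genes, protocadherins and both imprinted lists therefore do not measure a part due to GC. GC content is argued against there only as the whole cause. For germline genes, whose windows had 41.5% GC, it stays open. Copies missing from the assembly were not tested for these families and stay open.

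The dense domain from Ugt1a to Trpm8 was weighed against extra copies of the region in the embryos' genome, which would raise signal and background together. Its peaks had a median −log10 p 2.71 times that of peaks of nearest signal value, with quartiles of 2.31 and 3.05, whereas the ratio in the gamma protocadherin domain was 1. A high ratio points to raised background only if the signal value is relative to background, and its scale is not stated. The domain's peaks were also wider, at a median of 1148 bp against 311 bp in other replicated peaks on chromosomes. Width was not matched, so the ratio cannot decide whether extra copies relative to the reference account for this domain. Read depth in input DNA, not analysed here, would test it. Sequence repeated within the assembly is argued against by 1.04% of repeated 31-mers, against 4.39% in other replicated peaks on chromosomes. No biological explanation was tested, since the design has 1 group.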
